A study of Homo sapiens with 8 samples.

How the data were processed

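Biotin-labelled total RNA of human cells was hybridised to Affymetrix GeneChip arrays, per the labels' protocols. The authors deposited one table of log2 expression values with a value for each probe set on each of 8 arrays. These log2 values were made with GCRMA, a method that corrects the background by probe sequence, normalises between arrays by quantiles and summarises the probes of each probe set, per the submitters' processing notes, which give no version. The log2 scale was read from the deposited values, which share a floor of 2.16 on every array. How the 31232 probe sets of the table were chosen is not given in the sources used here.

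The groups came from the sample labels. They were dendritic cells alone (1 array), melanocytes alone (4 arrays, numbered 1, 2, 4 and 5 in their titles) and melanocytes after coculture at 2 melanocytes per dendritic cell (3 arrays). Coculture arrays 4 and 5 carry those melanocyte numbers in their titles. The title of the remaining coculture has no number, and the array is called coculture 1 only as a name that pairs it with nothing. Every column of the table belonged to a sample with a group. The highest correlation of any 2 arrays over probe sets was 0.991, so no array was a copy of another. A check for mixed-up samples on the 2 pairs that share a title number found 0 pairs that did not match.

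Gene names came from the platform annotation, with symbols updated through gene identifiers. Of the 31232 probe sets, 25973 had 1 gene symbol, 1218 had several and 4041 were not listed there. Only probe sets with 1 symbol were named, and each of the 13421 genes was represented by its probe set with the highest mean over the 8 arrays. Genes with no array at or above 5 on the log2 scale were left out, which kept 12299 genes for testing. Expression on arrays gives no read depth, and the number of arrays limits the precision of each comparison.

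Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in one model of 3 groups over all 8 arrays. P-values were two-sided and adjusted by Benjamini-Hochberg over the 12299 genes, with a threshold of 0.05. The lone dendritic cell array adds no estimate of its own spread, so every test that involves it assumes that dendritic cells vary like the other groups. A gene was called outside both cell types when the coculture differed in the same direction from melanocytes and from dendritic cells, with the larger of the 2 p-values adjusted over all genes.

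The 24 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. Fry results are given only for cocultures against melanocytes. The cell type lists covered melanocyte identity and pigmentation, monocyte-derived dendritic cells, all leukocytes, monocytes and macrophages, T, NK and B cells, keratinocytes, fibroblasts and endothelium. The process lists covered NF-kB-driven cytokines and chemokines, the type I interferon and interferon gamma responses, MHC class I and class II antigen presentation, cell cycle, extracellular matrix and proteases, cell adhesion, neural crest and dedifferentiation, hypoxia and glycolysis, cholesterol synthesis, the unfolded protein response with amino acid stress, p53 targets and cell death, metallothioneins and oxidative stress, growth factor receptor and MAPK feedback, and reference genes.

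The genes to be named were set by a rule. In the coculture and melanocyte comparison the rule took the genes past the threshold whose cocultures all lay outside the range of the melanocyte arrays, ranked by size, or those with the smallest p in a direction where none passed. For the other comparisons it took the largest differences in each direction, and from each list the members with the largest difference past the threshold or, where none passed, the 2 with the smallest p. Genes on the Y chromosome and XIST were never named. The groups, lists, tests, this rule and a set of alternative settings were fixed before the data were examined.

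The share of dendritic cell RNA in each coculture array was estimated on the linear scale as the median over signature genes of the coculture's excess above melanocytes divided by that of the dendritic cell array. Signature genes were those at or above 8 in the dendritic cell array and at or below 4 in the melanocyte mean, both on the log2 scale. Each melanocyte array was scored in the same way against the other melanocyte arrays, and the groups were compared by an exact one-sided permutation test.

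Title numbers 4 and 5 were taken to pair coculture and melanocyte arrays, because the coculture titles name the melanocyte number. The labels do not state a donor, and this decision was settled after first fits with and without the pairing had been seen. Deviations from the group means correlated at 0.750 within number 4 and at 0.752 within number 5, against 0.196 for coculture 5 with melanocyte 4 and 0.110 for coculture 4 with melanocyte 5. The unnumbered coculture 1 correlated with melanocyte 1 at 0.775 and with melanocyte 2 at 0.548. Results with the title number as a random block (duplicateCorrelation, unshared arrays as blocks of their own) are given beside the main ones. They are counts for lists and, for some of the genes whose call the block changes, values.

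The alternative settings fixed then changed the filter on dim genes, the choice among a gene's probe sets, the normalisation between arrays, the variance model, the arrays in the fit, the replicate block, the signature genes and the size threshold, added dendritic cell RNA to the melanocyte arrays on the computer, and left out each melanocyte and coculture array in turn. Chosen after seeing the data were the array set as a term, each array set alone, a mix at a share of 3%, signature genes at or above 13, lists without the members brighter in dendritic cells by over 1 on the log2 scale, and the random block with arrays left out.

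The model was tested on simulated data for the comparison of cocultures with melanocytes over the 12299 genes. With independent arrays, 19.4% of genes changed by 1 on the log2 scale, 50.7% of those changed by 2 and 74.2% of those changed by 3 were recovered, with 7 false calls. With arrays of one title number correlated at 0.9, the random block recovered 70.1%, 89.6% and 97.0% with 17 false calls, and the model without it 19.4%, 49.3% and 74.2% with 0 false calls. The simulated arrays formed no sets, and coculture 1 was drawn independently of melanocytes 1 and 2. The real arrays differ in both respects, so these rates may not hold for them. A simulated shift of 1 list by 1 on the log2 scale was found by camera (limma, Benjamini-Hochberg adjusted p = 3.45e-19), with 0 of the other lists called. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.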

Results

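Human dendritic cells, the antigen-presenting cells of the immune system, and melanocytes, the pigment cells of the epidermis, were profiled on arrays alone and after the melanocytes had been cocultured with dendritic cells. The set held 1 array of dendritic cells, 4 of melanocytes and 3 of cocultures, the last set up with 2 melanocytes per dendritic cell. Across the 8 arrays the median log2 level lay between 7.81 and 8.09, and 69.6% to 71.5% of the 31232 probe sets were at or above 5. Every array had the same floor of 2.16, so the difference from a group at the floor is limited by it. The labels do not say that replicates came from separate cultures or donors, and p-values then measure only the spread between these arrays, which may be technical. In the main model this spread also holds the difference between 2 sets of arrays described below, and the pairing by title number is not used.

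Dendritic cells and melanocytes were compared first, to give the background against which the cocultures can be read. The dendritic cell array was far higher in leukocyte and myeloid transcripts, led by the chemokine CCL22 (12.75 ± 1.26, log2 difference ± SE, 1 dendritic cell and 4 melanocyte arrays), the signalling adaptor TYROBP (12.69 ± 0.54), the lysosomal protein LAPTM5 (12.60 ± 0.52) and CHI3L1 (12.57 ± 2.15). RNASE1, SLAMF8, PECAM1, CXCR4, CD53 and S100A8 completed the 10 largest rises, at 12.24 to 12.47. Pigment cell genes were lower by nearly as much, with MLANA at -12.35 ± 0.12, the melanin enzymes TYR at -12.17 ± 0.20 and TYRP1 at -11.92 ± 0.28, and the lineage factor SOX10 at -11.85 ± 0.19, followed by OCA2, TFAP2A, BACE2, GYG2, MLPH and PMEL. In the limma model, 2196 of 12299 genes were higher and 3317 lower at a Benjamini-Hochberg adjusted p of 0.05, under the assumption that the single dendritic cell array varies like the other groups. Over all genes the median difference was -0.27. With each array centred on its median, 2592 genes were higher and 2850 lower.

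By group, all 16 tested monocyte and macrophage genes were higher in the dendritic cell array, such as CD163 (11.74) and the complement genes C1QB (11.40) and C1QA (11.38). So were 22 of 24 pan-leukocyte genes, 19 of 23 monocyte-derived dendritic cell genes, among them CD86 (11.54) and the migration receptor CCR7 (11.09), and all 12 MHC class II genes, among them HLA-DQA1 (10.73). Of 28 NF-kB-driven genes 18 were higher, with IL1B at 11.85 and IL1A at 9.27, and of 17 interferon gamma response genes 11 were higher and 1 was lower, with IDO1 at 11.59. Transcripts of lymphocytes were present in this preparation too: 9 of 15 T, NK and B cell genes were higher, including the cytotoxic granule genes GNLY (9.52) and PRF1 (8.91) and the B cell gene MS4A1 (8.75). Adjusted over the list alone, these counts were 16, 22, 19, 12, 18, 11 and 1, and 11 for the T, NK and B cell list.

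Melanocytes were the higher side in 27 of 31 melanocyte identity genes, in 27 of 30 cell cycle genes, with RRM2 at -10.89 and CCNB1 at -9.98, and in 18 of 28 type I interferon genes. Interferon-induced IFIT1 stood at 13.27 ± 0.22 (SD, n = 4) in melanocytes and at 3.39 in dendritic cells, and IFI44L at 12.07 ± 0.36 and 2.33. Adjusted over the list alone the counts were 28, 27 and 18. Metallothionein and oxidative stress genes were higher in dendritic cells for 8 of 16 members and lower for 1, with MT1M at 5.99 and MT1F at 2.53, and the counts were 8 and 1 adjusted over the list alone. Of the 24 lists, 11 passed the threshold with the preset correlation (camera in limma, Benjamini-Hochberg), and with an estimated correlation only the monocyte-derived dendritic cell list did, at an adjusted p = 0.0112. The melanocyte list then had an adjusted p = 0.170, the monocyte and macrophage list 0.170, the pan-leukocyte and interferon gamma lists 0.278, the T, NK and B cell list 0.300, the NF-kB list 0.301, the MHC class II and type I interferon lists 0.465, and the cell cycle and metallothionein lists 0.565.

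Before the cocultures were compared with melanocytes, the 7 arrays of those groups were set against each other. They fell into 2 sets, the 4 arrays with title numbers 4 and 5 and the other 3 arrays, on a first principal component with 60.4% of the variance. Each numbered coculture lay next to its melanocyte array, with correlations over probe sets of 0.990 within number 4 and 0.991 within number 5, and coculture 1 correlated with melanocyte 1 at 0.976. Melanocytes 1 and 2, which carry different numbers, correlated at 0.990 too, so such a value does not mark a shared number. Between the sets, 3607 genes differed in limma at an adjusted p of 0.05 (Benjamini-Hochberg). Cocultures 4 and 5 belong to the first set and only coculture 1 to the other, while the melanocyte arrays are split evenly. A set difference therefore enters the comparison of cocultures with melanocytes in the model without block.

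**Figure D1:**
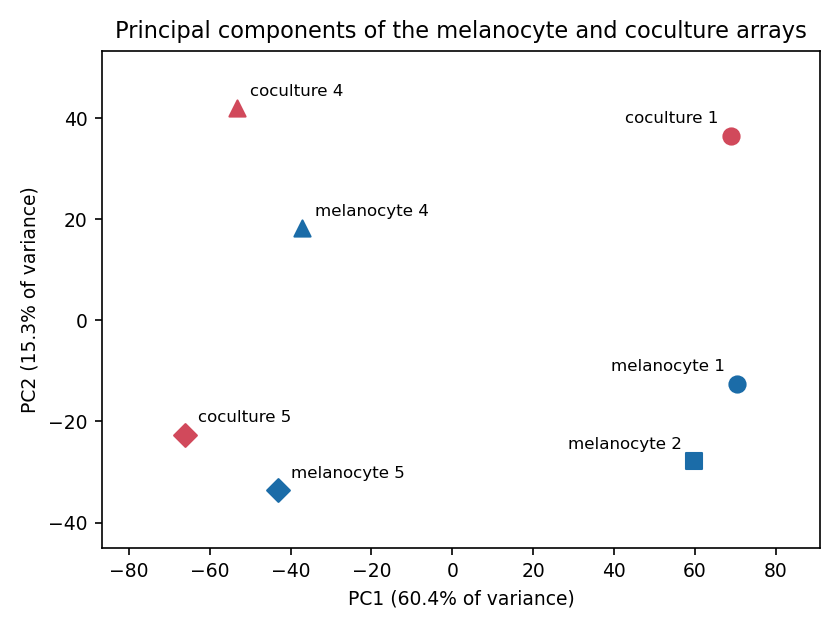
Principal components of the 7 melanocyte and coculture arrays over the 12299 genes tested, one point per array, with the share of variance on each axis and colour for the group. The first component (60.4%) parts the arrays with title numbers 4 and 5 from the other 3, and the second has 15.3%.

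The main comparison asked which genes differed between melanocytes cocultured with dendritic cells and melanocytes kept alone. 10 genes rose. They were the chemokine receptor CXCR4, the cytotoxic granule genes PRF1 and GNLY, the leukocyte lysosomal protein LAPTM5, the cytokine IL32, the secreted ribonuclease RNASE1, the T cell receptor adaptor SLA2, the protease inhibitor CST7, the adaptor TYROBP and ARHGAP9. CXCR4 went from 2.91 ± 0.90 (SD, n = 4) to 13.23 ± 1.03 (SD, n = 3), a log2 difference of 10.32 ± 0.68 (SE) with a limma adjusted p = 0.0102 (Benjamini-Hochberg). PRF1 rose by 7.76 ± 0.31 (limma adjusted p = 0.00115) and IL32 by 6.11 ± 0.19 (limma adjusted p = 0.000480). The other rises were 6.82 for LAPTM5, 6.42 for GNLY, 5.76 for RNASE1, 5.65 for SLA2, 4.88 for CST7, 4.35 for TYROBP and 1.90 for ARHGAP9, each in 3 of 3 cocultures. No gene fell at the threshold, a count of 0 in limma against 32 lower and 207 higher genes at an unadjusted p under 0.05. These are a smaller share of the 12299 genes than the 0.05 that chance alone would give, so they point to no further differences. The difference between the array sets is part of the spread in this model. HMGN3-AS1 had the smallest p of a lower value, at -1.25 ± 0.18 with a limma adjusted p = 0.288. SMAD9 stood at -1.84, SNX9 at -0.31, ADCY2 at -1.13, JAG1 at -0.51 and RFLNB at -0.56, all at an adjusted p of 1. All 3 cocultures lay above all 4 melanocyte arrays in 219 genes and below them in 63, together 2.29% of genes. Chance gives 5.71% for 7 exchangeable arrays, which these are not because they form 2 sets, so the shares cannot be compared directly.

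All 10 rises were also called higher in the dendritic cell array than in melanocytes. Independent lists of these sizes would share 1.79, a value that leaves out the shared melanocyte arrays. Simulated unchanged groups against the same arrays shared 0 on average in 20 data sets, but with only 0.05 coculture rises called they set no bound. Over all genes the difference of cocultures from melanocytes correlated with that of dendritic cells at r = 0.325. Genes are not independent replicates. Simulated unchanged groups gave 0.292, but they held no difference between dendritic cells and melanocytes, so this r cannot be compared with the observed one. The covariance was 0.553 against 0.136 in the simulation, which drew independent arrays without the array sets. With the melanocyte arrays split so that no array served both comparisons, r was 0.241 and 0.315 and the covariance 0.438 and 0.582. With only 2 melanocyte arrays on each side, limma called 0 genes higher in the cocultures in either split, with 83 and 88 at an unadjusted p under 0.05.

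With the title number as a random block (consensus correlation 0.904), limma called 166 genes higher and 7 lower, and the 10 rises were among the 166. At an unadjusted p under 0.05 there were 811 higher and 472 lower genes. Of the 12 splits of the arrays that part both numbers, 3, the real one included, gave at least the real 173 genes with the block. The highest other split gave 220, so chance cannot be excluded for the counts called with the block, here and below. The largest further rises, named after their values were seen, were the leukocyte phosphatase PTPRC (7.74 ± 0.47, SE, adjusted p = 0.00239), the tetraspanin CD53 (7.73 ± 0.33), the T cell receptor constant chain TRBC1 (7.06 ± 0.48), CHI3L1 (6.62 ± 0.62), the lymphoid factor IKZF1 (6.18 ± 0.61), the scavenger receptor CD163 (6.13 ± 0.56) and P2RY8 (6.05 ± 0.54). Of the 166, 149 were also called higher in the dendritic cell array, where independent lists would share 29.6, again without regard to the shared melanocyte arrays. In 20 simulated data sets of unchanged groups 0 were shared, but with 0 called they set no bound. With melanocytes 4 and 5 for the cocultures and melanocytes 1 and 2 for the dendritic cells, the block called 4 genes higher in limma (513 unadjusted), and all 4 were among the dendritic cell rises, where independent lists would share 0.615. The block also called 5 genes whose dendritic cell level did not exceed that of melanocytes, named after their values were seen. They were WWC1 (1.78 ± 0.25), FDCSP (1.49 ± 0.19), the complement protease C1S (1.12 ± 0.15), KCNIP4 (0.79 ± 0.11) and ZDHHC23 (0.64 ± 0.10). The 7 lower genes were SPART-AS1 (-1.56), HMGN3-AS1 (-1.18), CELF6 (-1.16), ZNF250 (-0.41), the melanosome biogenesis gene HPS4 (-0.30), SNX9 (-0.29) and METTL9 (-0.19). As a fixed term, which leaves only the pairs of numbers 4 and 5 to carry the difference, the number gave 0 calls in limma, with 648 higher and 320 lower genes at an unadjusted p under 0.05. The count of 10 higher genes became 4, 2, 6 and 4 without melanocyte 1, 2, 4 and 5 and 86 without coculture 1. Only IL32 and PRF1 were called whichever array was left out. With the mean of a gene's probe sets 4 of the 10 lost their call: CXCR4 (4.65, adjusted p = 0.303), LAPTM5 (4.71, 0.116), GNLY (6.16, 0.0759) and ARHGAP9 (1.72, 0.145). With the array set as a term, GNLY, RNASE1, CST7 and TYROBP lost theirs at adjusted p-values of 0.0536 to 0.0733, with differences of 6.33, 5.77, 4.88 and 4.35. With the block, 32 genes were higher and 1 lower without melanocyte 1, and 109 and 3 without melanocyte 2.

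Among cell type lists, markers of blood cells were higher in the cocultures. Pan-leukocyte genes had a median log2 difference of 1.43, with 21 of 24 members positive, 2 called (LAPTM5 and TYROBP), 7 called when adjusted over the list alone and 13 called with the block. T, NK and B cell genes had a median of 2.15, with 13 of 15 positive, 2 called (PRF1 and GNLY), 3 adjusted over the list alone and 7 with the block. Monocyte and macrophage genes had a median of 0.83 with 12 of 16 positive, and 0 called, 1 adjusted over the list alone and 7 with the block, S100A8 standing at 4.87 and CD163 at 4.63. Camera adjusted p-values were 3.32e-24, 2.80e-16 and 2.48e-09, and 0.112, 0.112 and 0.116 with an estimated correlation. The monocyte-derived dendritic cell list had a median of 0.00 and a mean of 0.48, with 10 members positive and 8 negative, 0 called and 0 adjusted over the list alone. It passed at an adjusted p = 0.0316, or 0.133 with an estimated correlation. In that list CCL22 stood at 3.19 ± 0.86 and the mannose receptor MRC1 at 3.29 ± 1.13, and only MRC1 was called with the block (4.55, adjusted p = 0.0151).

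Levels of these markers were uneven over the cocultures. At or above a log2 level of 5 were 11 of 15 T, NK and B cell genes in coculture 4, 8 in coculture 5 and 6 in coculture 1, against 2 or 3 in each melanocyte array and 15 in the dendritic cell array. For monocyte and macrophage genes the counts were 6, 5 and 3 of 16, against 0 or 1 in each melanocyte array and 16 in the dendritic cell array. The T cell gene TRBC1 stood at 10.27 in coculture 4, 8.75 in coculture 5 and 5.98 in coculture 1, beside 10.14 in dendritic cells, and CD8A at 7.42, 6.39 and 2.16, beside 6.66. The myeloid gene S100A8 was at 8.83, 8.09 and 5.13 in the same order, and at 14.72 in dendritic cells. CCL22 was highest in coculture 1, at 7.75, against 4.82 in coculture 4, with coculture 5 lower still. No difference between single cocultures was tested.

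**Figure D2:**
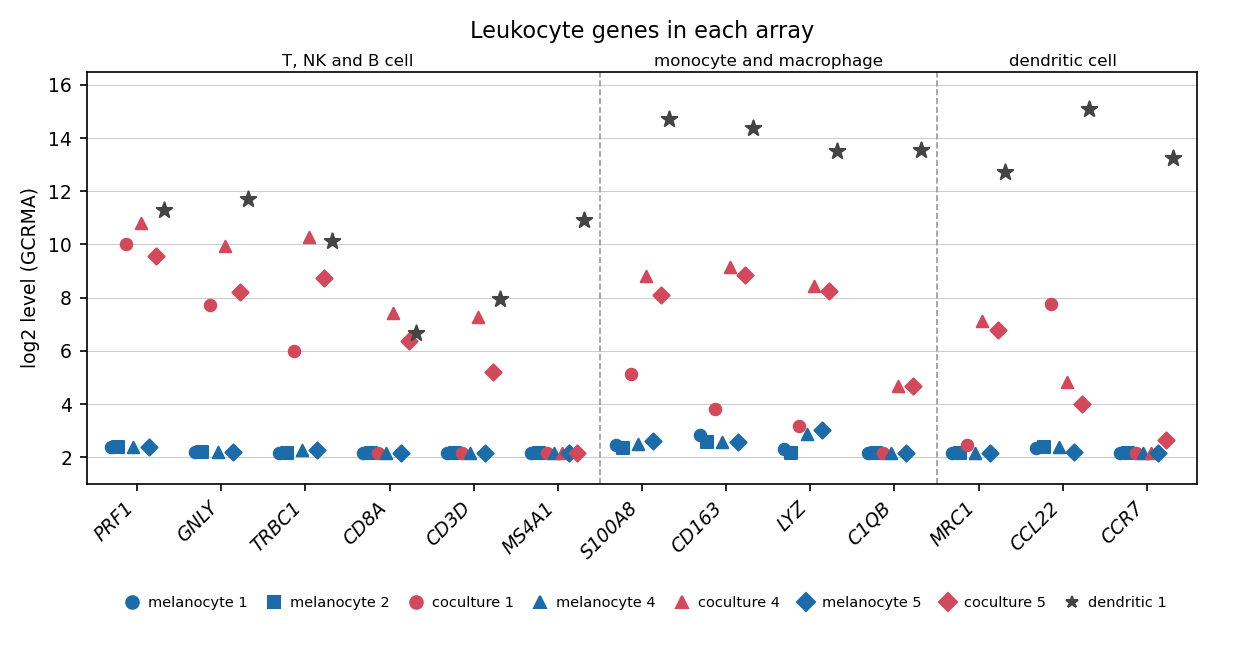
Log2 levels of leukocyte genes on each array, grouped as T, NK and B cell genes, monocyte and macrophage genes and dendritic cell genes, with one point per array and the 8 arrays set side by side. PRF1 lies near the floor in melanocytes and at 10.13 ± 0.63 (SD, n = 3) in the cocultures, close to 11.29 in dendritic cells, while CCR7 stays near the floor in the cocultures against 13.25 in dendritic cells.

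Inflammatory genes were higher in the cocultures as lists, in the same arrays in which leukocyte markers were higher. NF-kB-driven cytokines and chemokines had a median log2 difference of 1.13 with 27 of 28 members positive and 0 called, 1 adjusted over the list alone and 8 with the block. The 8 were the chemokines CCL2, CCL4, CCL5 and CCL8, IL1B, the adhesion molecule ICAM1, the NF-kB inhibitor NFKBIA and the superoxide dismutase SOD2. Of these, CCL2 (-0.67), CCL8 (-0.31) and IL1B (0.00) were not higher in coculture 1 than in melanocytes 1 and 2. ICAM1 was at 11.06 ± 0.08 (SD, n = 4) in melanocytes and at 11.83 ± 0.22 (SD, n = 3) in cocultures, with a limma adjusted p = 0.360 without the block and 0.0115 with it, and CCL5 stood at 2.03 ± 0.48 (SE). The interferon gamma list had a median of 0.74 with 16 of 17 positive, 0 called, 3 adjusted over the list alone and 4 with the block, namely IDO1, APOL1, APOL3 and ICAM1. Within number 4, within number 5 and for coculture 1 the medians were 0.59, 0.71 and 0.32 for the NF-kB list and 0.58, 0.83 and 0.29 for the interferon gamma list. Camera adjusted p-values were 2.29e-13 and 1.10e-09, and both were 0.112 with an estimated correlation. Chosen after their values were seen, the complement genes C3 (1.93 ± 0.43, SE) and CFB (2.01 ± 0.61) and the cytokine signalling inhibitor SOCS3 (1.11 ± 0.31) were called only with the block, at limma adjusted p-values of 0.0214, 0.0362 and 0.0115. Without the members brighter in dendritic cells by over 1 on the log2 scale, both lists still passed at a camera adjusted p = 0.0192, with 5 and 6 members left.

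**Figure D3:**
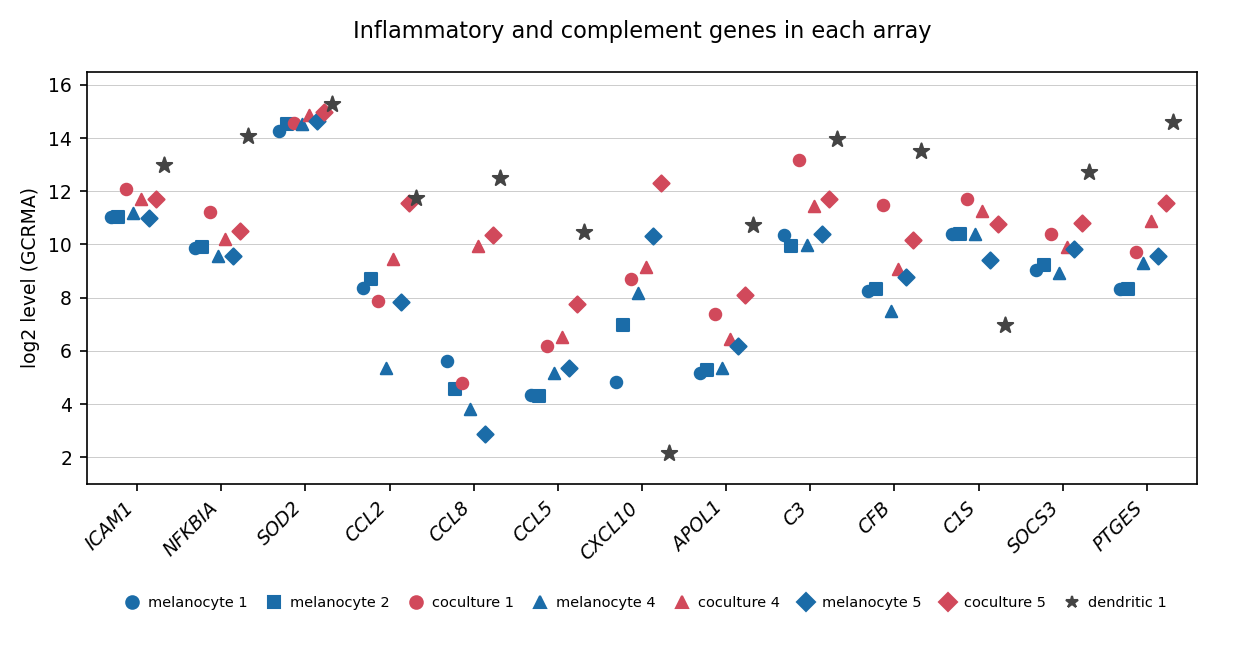
Log2 levels of inflammatory and complement genes on each array, one point per array, with the groups in colour. ICAM1 stood at 11.06 ± 0.08 (SD, n = 4) in melanocytes, 11.83 ± 0.22 (SD, n = 3) in cocultures and 13.01 in dendritic cells, and C1S at 10.15, 11.26 and 6.98.

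Melanocyte identity and pigmentation genes were slightly lower as a list. Their median log2 difference was -0.18, with 26 of 31 members negative and 0 called, 0 adjusted over the list alone and 1 with the block (HPS4). Camera gave an adjusted p = 5.79e-08, or 0.128 with an estimated correlation. MITF, the master regulator of the lineage, stood at -0.19 ± 0.08 (SE) with a limma adjusted p of 1. Within number 4, within number 5 and for coculture 1 the list medians were -0.14, -0.16 and -0.12. The pan-leukocyte markers of the same arrays stood higher, with medians of 1.89, 1.30 and 0.30.

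Antigen presentation lists were higher, in the arrays that also held leukocyte transcripts. The class I rise did not follow the pan-leukocyte medians, which were 1.89 and 1.30 within numbers 4 and 5 and 0.30 for coculture 1. It was largest for coculture 1. MHC class I genes had a median of 0.29 with 15 of 16 positive, PSMB9 at 0.34 ± 0.14 and NLRC5 at 0.45 ± 0.18, a camera adjusted p = 0.000356 and 0.112 with an estimated correlation. That list did not pass without probe sets of shared sequence (0.0818, 11 members), with array weights (0.110), with the fixed replicate block (0.190) or with dendritic cell RNA mixed into the melanocytes at 3% (0.634). MHC class II genes had a median of 0.78 with 11 of 12 positive, the invariant chain CD74 at 1.17 ± 0.54 and HLA-DMB at 1.12 ± 0.56, an adjusted p = 0.00491 and 0.440 with an estimated correlation, and 3 were called with the block (HLA-DQB1, CD74 and CTSS). The MHC class II list passed neither without coculture 1 (camera adjusted p = 0.413) nor without melanocyte 4 or 5. Array weights also ended its call (0.0537). Dendritic cell RNA mixed in at 3% turned it downward (0.921), because the mix raises these genes in the melanocyte arrays. The 3% mix lies above every mean share estimated from signature genes, so it tests neither list at those shares. Within number 4, within number 5 and for coculture 1 the medians were 0.06, 0.18 and 0.43 for class I and 1.503, 0.69 and 0.43 for class II. In both lists 0 members were called, also adjusted over the list alone.

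Cell cycle genes had a median of 0.44 with all 30 positive and 0 called, a camera adjusted p = 0.000581 and 0.541 with an estimated correlation. Within number 4 and number 5 the median was 0.04 and 0.01, and it was 0.47 for coculture 1 against melanocytes 1 and 2. Melanocytes 4 and 5 stood above melanocytes 1 and 2 by a median of 1.63 in this list. The sets are unequally shared between the groups, so the 0.44 includes a set difference and cannot be read as an effect of coculture alone. With the block the list did not pass (adjusted p = 0.613). Type I interferon genes had a median of 0.23 with 22 of 28 positive (OASL 0.87 ± 0.38, IRF7 0.64 ± 0.35). Their medians were -0.18, 0.34 and 0.28 within number 4, within number 5 and for coculture 1, and the list had an adjusted p = 0.0132, 0.510 with an estimated correlation and 0.215 with the block. The direction of the type I interferon list turned downward with array weights (0.268) and without coculture 5 (0.610). It also missed the threshold without melanocyte 1 (0.284) and without coculture 1 (0.0523). Extracellular matrix and protease genes (median 0.27, MMP9 at 0.83 ± 0.31 and PLAUR at 0.73 ± 0.32) passed at 0.00128 and the 2 tested endothelial genes (PECAM1 at 3.62 ± 0.84, EGFL7 at 0.42 ± 0.70) at 0.0132, against 0.355 and 0.128 with an estimated correlation. With the block MMP9 and PECAM1 were called higher. EGFL7 turned negative with the block (-0.18), with array weights (-0.60) and without coculture 1 (-0.39).

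Growth factor receptor and MAPK feedback genes (median 0.59, DUSP4 at 0.28 ± 0.14 and EREG at 1.90 ± 1.07) had an adjusted p = 0.0102, neural crest and dedifferentiation genes (median 0.61, NGFR at 2.30 ± 0.80 and SNAI2 at -0.68 ± 0.31) 0.0246 and hypoxia and glycolysis genes (median 0.11, KDM3A at 0.31 ± 0.16 and ANGPTL4 at 3.58 ± 1.94) 0.0451, all upward. With an estimated correlation these were 0.510, 0.440 and 0.440, and with the block 0.215, 0.349 and 0.433. Of the members of these lists, only EREG was called with the block, as higher. Within number 4, within number 5 and for coculture 1 the medians were 0.03, 0.16 and 0.36 for the MAPK feedback list and 0.19, 0.17 and 0.10 for the neural crest list. Melanocytes 4 and 5 stood above melanocytes 1 and 2 by medians of 1.16 and 1.51 in these lists. Their medians over all arrays therefore also include a set difference. Cholesterol synthesis genes were lower (median -0.18, IDI1 at -0.33 ± 0.16 and ACAT2 at -0.33 ± 0.21) at an adjusted p = 0.0451, or 0.172 with an estimated correlation and 0.529 with the block. Without the block 0 members of the lists from cell cycle to cholesterol synthesis were called, and adjusted over the list alone only PECAM1 was. The lists of cell adhesion (median 0.10), keratinocyte (0.68), fibroblast (0.69), metallothionein and oxidative stress (0.07), unfolded protein response and amino acid stress (0.17), p53 targets and cell death (-0.03) and reference genes (0.03) did not pass, at camera adjusted p-values of 0.178 to 0.514. Some passed upward under single settings. The metallothionein list did without coculture 1 (0.0194), the unfolded protein response list without melanocyte 4 (0.0472), and the keratinocyte list without melanocyte 5 (0.04996) and without probe sets of shared sequence (0.0432). The fibroblast list passed upward without melanocyte 4 (0.00710) and with array weights (0.0379), and turned downward without coculture 4 (0.196) or melanocyte 5 (0.908). Its medians were 0 within number 4, 0.03 within number 5 and 0.0034 for coculture 1, so its 0.69 over all arrays did not appear within the sets.

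Of the 24 lists, 17 passed with the preset correlation, 15 upward and 2 downward, 0 with an estimated correlation, and 11 with the block. Whichever array was left out, 7 of the 17 passed, namely the pan-leukocyte, T, NK and B cell, monocyte and macrophage, NF-kB, interferon gamma, MHC class I and melanocyte lists. The other 10 did not, and 10 lists passed without melanocyte 1 and 11 without coculture 4 or coculture 5. Without the members brighter in dendritic cells by over 1 on the log2 scale, the extracellular matrix and protease and the MAPK feedback lists no longer passed (camera adjusted p = 0.136 for both). Nor did the type I interferon (0.0731), neural crest (0.0769), cholesterol (0.0665), hypoxia (0.517) and endothelial (0.731) lists. The pan-leukocyte, T, NK and B cell and monocyte-derived dendritic cell lists kept 1, 1 and 2 members and did not pass (0.393, 0.790 and 0.488). No members of the monocyte and macrophage or the MHC class II list were left. The MHC class I (0.0192), cell cycle (0.00213) and melanocyte (3.18e-07) lists passed. With fry over all tested members, the endothelial list passed at a Benjamini-Hochberg adjusted p = 0.00711. So did the T, NK and B cell (0.0157), monocyte-derived dendritic cell (0.0161) and pan-leukocyte (0.0232) lists. No other list passed with fry. The interferon gamma list was at 0.0750, the NF-kB, MHC class I and monocyte and macrophage lists at 0.0774, the melanocyte list at 0.240 and the cell cycle list at 0.578.

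**Figure D4:**
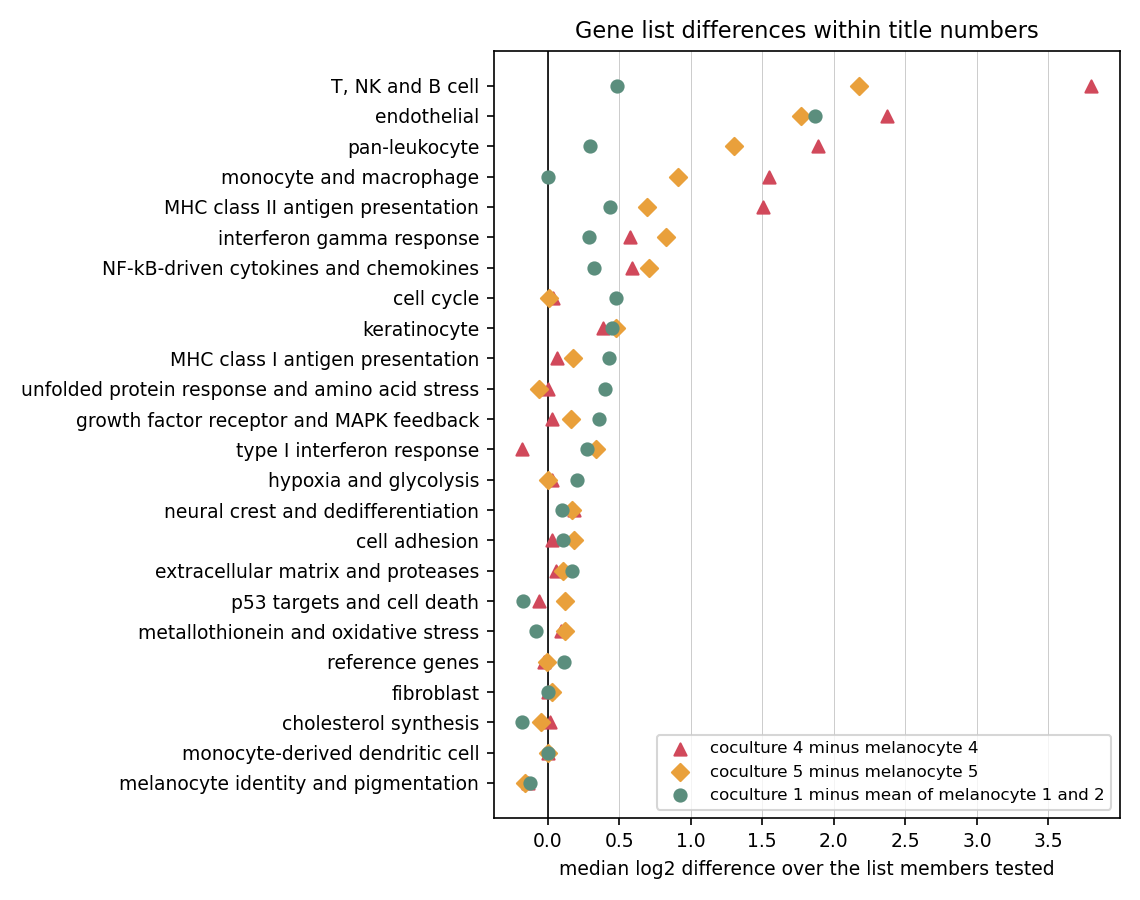
Median log2 difference over the tested members of each of the 24 gene lists, within title number 4, within number 5 and for coculture 1 against the mean of melanocytes 1 and 2. The T, NK and B cell list stands at 3.80, 2.18 and 0.49 and the melanocyte list at -0.14, -0.16 and -0.12.

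Cocultures were next compared with dendritic cells. Pigment cell genes were higher in the cocultures by about as much as in melanocytes, with MLANA at 12.26 ± 0.13 (log2 difference ± SE), TYR at 11.99 ± 0.21, SOX10 at 11.88 ± 0.19, TYRP1 at 11.82 ± 0.29 and the secreted peptide gene FDCSP at 11.81 ± 0.59. Lower were AIF1, a calcium-binding protein of macrophages, at -11.71 ± 0.21, CD93 at -11.71 ± 0.07, RNF175 at -11.45 ± 0.09, SLC43A2 at -11.36 ± 0.32 and MUCL1 at -11.26 ± 0.23. In limma 3155 genes were higher and 1970 lower at a Benjamini-Hochberg adjusted p of 0.05, again with 1 dendritic cell array assumed to vary like the others. With median centring the counts were 2680 and 2425. Of the 24 lists 12 passed with the preset correlation, 4 upward (melanocyte, cell cycle, type I interferon and neural crest) and 8 downward, and 1 with an estimated correlation, the monocyte-derived dendritic cell list (adjusted p = 0.0106). Higher in the cocultures were 26 of 31 melanocyte genes, 27 of 30 cell cycle genes, 18 of 28 type I interferon genes and 8 of 18 neural crest genes, and 27, 28, 20 and 8 adjusted over the list alone. Lower were 15 of 16 monocyte and macrophage genes, 22 of 24 pan-leukocyte genes, 18 of 23 monocyte-derived dendritic cell genes, all 12 MHC class II genes and 15 of 28 NF-kB genes, and 16, 22, 19, 12 and 15 adjusted over the list alone. Only 5 of 15 T, NK and B cell genes were lower, also 5 adjusted over the list alone. Of the interferon gamma genes 11 were lower and 2 higher (11 and 3 adjusted over the list alone), and of the metallothionein and oxidative stress genes 8 and 1 (the same adjusted over the list alone). With an estimated correlation the adjusted p was 0.186 for the melanocyte and monocyte lists, 0.331 for the pan-leukocyte and interferon gamma lists, 0.417 for the MHC class II, NF-kB, T, NK and B cell and type I interferon lists, 0.569 for cell cycle and neural crest and 0.611 for metallothioneins.

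A mixture of both RNAs would lie between them, so genes were also sought whose coculture level lay outside both cell types. There were 0 such genes above and 0 below in limma at a Benjamini-Hochberg adjusted p of 0.05, with 23 and 10 at an unadjusted p under 0.05, and 0 and 0 with the block (138 and 55 unadjusted). The 5 genes that the block called higher than in melanocytes, with a dendritic cell level not above melanocytes, lay above both by value. They did not pass this test. The largest values above both were those of the immediate early gene EGR1 (3.40 beyond the nearer group), CCN1 (3.31), SERPINA3 (2.69), IL13RA2 (2.52) and the chemokine CXCL10 (2.47), which was at 7.57 ± 2.30 in melanocytes, 10.05 ± 1.97 in cocultures and 2.16 in dendritic cells. FOSL1, NGFR, CXCL11, NHS and ART3 followed at 2.02 to 2.32. EGR1 was far higher in melanocytes 4 and 5 than in melanocytes 1 and 2, as given under the other observations. Its margin above the melanocyte mean therefore includes a difference between the array sets. Below both, RBM6 (-1.63), SNAP25 (-1.61), SLC27A3 (-1.49), SMG1P5 (-1.45), TRMT10B (-1.44), AP5B1 (-1.42), STAC (-1.30), GTF2H2B (-1.26), HMGN3-AS1 (-1.25) and PDK4 (-1.16) had the largest margins. All 20 of these had an adjusted p of 1.

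The share of dendritic cell RNA was estimated from 542 signature genes, since the labels name no step that separated the cells after coculture. It was 0.00316% ± 0.00547 (SD, n = 3) in the cocultures and 0 in each of the 4 melanocyte arrays (exact one-sided permutation p = 0.429, where 0.0286 is the smallest that 3 against 4 arrays allow). By array it was 0 in cocultures 1 and 5 and 0.00947% in coculture 4. Genes at the floor hold such a median at 0, so it does not bound the share shown by genes above the floor. The estimate also assumes that dendritic cell transcripts kept the levels of the single dendritic cell array. The interquartile mean over the same genes gave 0.0287% ± 0.0361 (exact p = 0.0286), and the 87 genes at or above 13 in dendritic cells gave 0.185% ± 0.189 (exact p = 0.0286). These p-values treat the arrays as exchangeable, which they are not because they form sets and pairs. Only 12 splits part both numbers, too few for a p under 0.05. With genes required at or above 5 on at least 3 arrays the share was 0.938%, but that filter favours signature genes raised in the cocultures, so a larger share follows from it. Without coculture 4 the share was 0.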

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

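The tests of uniform carry-over, of the share of dendritic cell RNA that inflammatory genes would need and of the list count over splits that part both numbers were chosen after the results had been seen, and the others before.

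In 9 of 149 results tested, 1 of the 4 melanocyte arrays lay far from the other 3, where chance gives 7.45. The results tested were levels of named genes, median levels of lists and the array median. Distance was judged by the gap over the range, so small gaps can count. Melanocyte 5 was below the others for TYR (14.20 against 14.50 to 14.53), OCA2 (13.76 against 14.18 to 14.24), PMEL (14.47 against 14.57 to 14.59), ADM (8.999 against 10.17 to 10.36), METTL9 (12.66 against 12.84 to 12.86) and C1S (9.41 against 10.38 to 10.41). Melanocyte 4 was below the others for the MHC class II regulator CIITA (3.55 against 6.48 to 6.79) and above them for CELF6 (6.01 against 4.87 to 4.96), and melanocyte 2 was below them for WWC1 (4.69 against 5.81 to 6.01).

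By median, 6 T, NK and B cell genes with a dendritic cell level of 8 to 12 stood closer to that array in the cocultures than random genes of that level. Only 2 monocyte and macrophage genes lay in the range, at -8.08, -7.66 and -8.08 in cocultures 1, 4 and 5, too few to compare. The B cell gene MS4A1 went the other way, at the floor in all 3 cocultures. Compression of dim probe sets was argued against: in 3 of 3 cocultures the median distance of 6 lymphocyte genes from that array (-5.26, -3.84 and -4.79) lay above 99.96%, 99.95% and 99.93% of the medians of random sets from 392 genes of like dendritic cell level. The same values argue against carry-over of the dendritic cell preparation in one proportion, at least 99.93% in each coculture, since it would leave both kinds of gene equally far from their own dendritic cell level, and the floor brings the random genes nearer (median dendritic cell level 10.01 against 10.80). This was the last of 3 tests of such carry-over: distances between the lists argued against it, their levels left it open (exact one-sided p = 0.0125, 0.113 and 0.225), and both were set aside because the floor decides the first and probe sets of different genes are not comparable in the second. A loss of the myeloid cells that left lymphocytes behind, lymphocytes from another source, or induction of these genes in the coculture may account for the pattern, and none of these was tested.

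Inflammatory genes that melanocytes express had higher values in the cocultures as a group, but the smallest adjusted p among the 18 was 0.360 (ICAM1), only CCL2, ICAM1, NFKBIA and SOD2 were called with the block, and their NF-kB and interferon gamma lists had an adjusted p = 0.112 with an estimated correlation. A difference between the array sets alone was argued against, since the median of 18 such genes was 0.54 within the set of numbers 4 and 5 and 0.499 in the other set, with 18 of 18 and 15 of 18 positive. Carry-over with the makeup of the dendritic cell array was argued against in cocultures 4 and 5, where 13 members would need a median share of 10.9% and 20.8% against the melanocytes of their number and 19.4% and 26.2% against all melanocytes, above the 90th percentile over bright signature genes (2.43% and 1.89%) and above the highest melanocyte array scored in the same ways (2.82% and 7.95%). For coculture 1 it stays open, because the share was 8.73% against melanocytes 1 and 2, a baseline taken after the other had been seen, but 1.29% against all melanocytes, below that 7.95%. Carry-over of another makeup or a response of the melanocytes to dendritic cells could also produce the pattern, and neither was tested.

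Over all 35 splits of the 7 arrays into 3 and 4, chance cannot be excluded for the 10 genes, because 2 splits gave as many, the other being the split that follows the array sets, with 4072 genes. A split with so many genes points to a structure of the samples other than coculture. For the 17 gene lists 1 split of those 35, the real one, gave as many, with 16 lists in the highest other split. Most of the 35 splits do not keep the pairing by number and the arrays form 2 sets, so this rank cannot exclude chance. Of the 12 splits that part both numbers, as the real one does, the highest other gave 13 lists and 0 genes, and 12 are too few for a share under 0.05. With the replicate block 3 of these 12, the real one included, gave at least the real 173 genes, the highest other giving 220. Chance therefore cannot be excluded for the counts called with the block.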

How the results depend on the processing

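The array set as a term, each array set alone, the mix at 3%, signature genes at or above 13, the lists without members brighter in dendritic cells and the replicate block with arrays left out were chosen after the data had been seen, and the other settings before. Of 3032 alternative values of 165 named gene results, 2864 kept their direction and their side of the threshold, 96 lost and 41 gained a call, and 31 changed sign. Array weights did not converge to tolerance, the replicate block could not be fitted with an array of number 4 or 5 left out, and levels near the floor limit every fold. Where no cause is named, the cause was not tested.

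Between cocultures and melanocytes, limma called 166 genes higher and 7 lower with the random replicate block, 0 higher with the fixed replicate block, which rests on 2 pairs, 155 and 3 with array weights, 14 higher in the arrays of titles 4 and 5 alone, with 0 of the 10 named rises among them, 126 and 12 in the other 3 arrays alone, with 9 of the 10, 7 and 1 with the array set as a term, and 5 and 682 with dendritic cell RNA mixed into the melanocytes at 3%. Leaving out each array in turn gave 2 to 86 higher and 0 lower (unadjusted 5 to 133), and with the block 32 to 141 higher and 1 to 8 lower. The count of 17 lists past the threshold became 11 with array weights, the random replicate block or the array set as a term, 10 with the fixed replicate block, 9 in either array set alone, 5 without members brighter in dendritic cells, 0 with an estimated correlation and 10 to 16 with an array left out. With the 3% mix it was 3, all turned downward: the pan-leukocyte (1.13e-05), monocyte and macrophage (8.60e-10) and monocyte-derived dendritic cell (1.77e-15) lists. The other 14 lost their call there, and the NF-kB (0.636), interferon gamma (0.634), T, NK and B cell (0.525), MHC class II (0.921), extracellular matrix (0.634), melanocyte (0.634) and cholesterol (0.636) lists changed direction. The 3% mix lies above every mean share estimated from signature genes and was added to the melanocyte arrays only. Falls of genes bright in dendritic cells therefore follow from it by construction. The planned mix at the estimated share kept all 10 named rises. Between dendritic cells and melanocytes, 1264 genes were higher when at least 3 arrays had to reach 5, and 3388 were higher and 5065 lower with array weights. Between cocultures and dendritic cells, 1092 were lower under that filter, and 5642 were higher and 3759 lower with array weights. The dendritic cell RNA share was 0.0160% with signature genes at or above 10, 0.0448% with the fixed lists, 0.0287% as an interquartile mean, 0.185% with genes at or above 13, 0.938% under the filter on 3 arrays, which by construction favours signature genes raised in the cocultures, and 0 to 0.00474% with an array left out.

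The 3% mix turned LAPTM5 to -0.72, RNASE1 to -1.66, CST7 to -1.70, TYROBP to -3.28, ARHGAP9 to -2.67, HLA-DMB to -0.42, PECAM1 to -3.64, MMP9 to -5.84, EREG to -2.13, S100A8 to -2.32, CD163 to -2.07, CCL22 to -4.51 and MRC1 to -2.23, because it adds their RNA to the melanocytes. With the fixed replicate block, and equally in the arrays of titles 4 and 5 alone, MCM5 was at -0.0245, TUBB at -0.0351, GUSB at -0.0121 and EGFL7 at -0.29. GUSB was at -0.21 with the mean of its probe sets, -0.10 with array weights and -0.0111 (without coculture 1) to 0.26 with an array left out. EGFL7 was at -0.60 with array weights, -0.18 with the random replicate block and -0.39 (without coculture 1) to 1.01 with an array left out. In the other 3 arrays alone FAP was at -0.31 and EREG at -0.0015. Between dendritic cells and melanocytes, IDI1 was at 0.71 without probe sets of shared sequence and PPIA at 0.0459 with median centring.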

Other observations

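The observations here were chosen after the data had been seen, apart from the gene lists.

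Some lymphocyte genes stood higher in cocultures 4 and 5 than in the dendritic cell array itself. The cytotoxic protease GZMA was at 6.24 in coculture 4 and 5.61 in coculture 5, beside 3.94 in dendritic cells, the T cell transcription factor BCL11B at 7.59 and 5.32 beside 3.28, and the activation marker CD69 at 8.53 and 7.98 beside 6.34. In coculture 1 GZMA and BCL11B were at the floor of 2.16, and CD69 at 3.82. The B cell gene MS4A1 was at the floor in all 3 cocultures, beside 10.91 in dendritic cells. No difference between single arrays was tested.

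Melanocyte arrays 4 and 5 differed from melanocytes 1 and 2 in several gene groups. All 30 cell cycle genes were higher in the first pair, with a median log2 difference of 1.63, as were 17 of 18 growth factor receptor and MAPK feedback genes (1.16) and 16 of 18 neural crest genes (1.51). All 12 MHC class II genes were lower (-1.40). The immediate early gene EGR1 was at 13.39 and 12.74 in melanocytes 4 and 5 and at 6.51 and 5.96 in melanocytes 1 and 2. These differences have 2 arrays on each side and were not tested. The 13 fibroblast genes stood apart in number 4 alone, with a median of 4.23 in melanocyte 4 and 5.03 in coculture 4 relative to the melanocyte mean, against -1.43 to -1.04 in the other 5 arrays.

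Of 3994 probe sets without a single gene name, limma called 0 higher and 0 lower in cocultures than in melanocytes, with 28 and 19 at an unadjusted p under 0.05, and 3 higher with the replicate block. The unadjusted counts are a smaller share than the 0.05 that chance alone would give.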
